A study of Mus musculus with 4 samples.

How the data were processed

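MIN6 cells were transfected with 10 µg of control plasmid or GR plasmid per dish, and RNA was taken 24 hours later, per the labels' protocols. Fragmented RNA was immunoprecipitated with an anti-m6A antibody, and the 2 IP libraries and 2 input libraries were sequenced in read pairs. The submitters' processing notes name BWA 0.7.12, HOMER 4.9.1 and the genome build mm10. The program that called differential peaks and its thresholds are not stated.

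The 4 files used hold comparisons of GR with control and no value per library. The autophagy table gives, per the file headers, the start and end of each peak, a log2 fold change deposited by the authors, and the gene part overlapped by the begin, centre and end of the peak. What the fold change was normalised to is not stated, nor is a p-value or an error per peak, and the sign was read from the name of the comparison (GR against control). In 3 lines the cells were separated by spaces, and lines were split on any white space. Gene symbols were carried down to lines that leave them out, and 1 pair of run-together gene parts (for Gabarapl1) was separated. The table has no chromosome, so chromosomes were taken by gene symbol from a RefSeq table of GRCm38.p6, the assembly that mm10 is made from, and all 31 peaks lay inside the bounds of their gene there. The gene table has no header and gives an Ensembl gene ID and a symbol per line, with no symbol for 3476 of 9225 IDs. Symbols were therefore taken from a table of gene IDs, which matched 9217 of them.

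The KEGG table holds p-values that the authors computed, per the file headers, with a hypergeometric or Fisher exact test and adjusted by Benjamini and Hochberg's method. It gives the input and background genes of each pathway and not the totals. Totals of 7193 input and 38668 background genes, found by search, gave back all 290 deposited p-values to within 1% in a one-sided Fisher test that treats input and background as separate samples. The GO table gives 4 counts per term with the authors' p-value and corrected p-value, and 63 overflow lines of long gene lists were joined to their terms. Hypergeometric p-values were recomputed from the 4 deposited counts.

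Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9. No test across conditions was possible with 1 library of each kind per arm. The design fixed before the data were examined had expected a full table of differential peaks with folds. Only the autophagy peaks have folds, so the share of lower peaks was computed for that table alone, and each of 18 gene lists (520 genes, all matched to protein-coding genes of the reference) was described by the share of its genes in the gene table. Each count was set against 10000 random lists with as many genes from each of 10 classes of gene length, and ties were counted at the middle rank. Intervals are exact Clopper-Pearson intervals at 95%.

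Autophagy genes were named by the rule of the 10 largest absolute folds with 1 peak per gene, and, as the rule also asked for every gene of the authors' table, the rest were added. No peak was higher, so no gene is named for that direction. The rule to name the largest rises and falls of each list could not be applied without folds, and list members were chosen after seeing their number of lines. KEGG pathways were the 10 with the smallest deposited p-value. The same rule for GO could not be applied because the deposited p-values are all 1.

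Alternatives were a limit of 1 on the absolute log2 fold change, genes in place of peaks, peaks without the widest 10%, merged peaks, 1 peak per gene, random lists without matching, other autophagy lists, recomputed p-values, and terms with 10 to 500 background genes. Those chosen after the data were seen are the end of the peak in place of its centre, matching by deposited symbol, the gene total of the GO table, each Entrez gene counted once, and the number of distinct IDs as the GO total.

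The calculations were tested on simulated data. Of 400 simulated unchanged lists among 21900 protein-coding genes, 4.50% lay above the 95th percentile, and of 200 lists with a doubled chance of being listed, 90.0% did. The simulated chance rose with gene length throughout. The real share was 17.4% in the longest class, below the highest of 32.6%. The search for the KEGG totals found both of 2 simulated pairs on the real pathway sizes. Of 200 GO terms with raised counts among 16568, 79.0% were called at an adjusted p below 0.05, with 3 of the other terms. The raised terms were drawn from larger terms only, with a gene total below both GO totals used here. The rate does not cover small terms such as mitophagy.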

Results

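N6-methyladenosine (m6A) on RNA was compared between MIN6 cells, a mouse insulinoma line used as a model of pancreatic beta cells, that had received a control vector or a vector expressing GR. The labels give the protein only by this abbreviation, which is read here as the glucocorticoid receptor. Each arm had 1 input library and 1 library from immunoprecipitation (IP) with an anti-m6A antibody, 4 libraries in all, from RNA taken 24 hours after transfection. With 1 library of each kind per arm, no difference below has a replicate check. The files used hold comparisons of the arms and no values per library, so the sequencing depth is unknown and the RNA level of a gene in the input could not be set beside its m6A change. The question is which transcripts gained or lost m6A when GR was expressed, and the authors singled out autophagy genes.

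The deposited autophagy table held 31 peaks in 22 genes, and all 31 had a negative log2 fold change, meaning a lower peak signal with GR as the table is named (GR against control); what the fold was normalised to is not stated. The exact Clopper-Pearson 95% interval of the share lower runs from 88.8% to 100% and covers counting error only. It treats the 31 peaks as independent, although 17 of them lay in the 8 genes with several peaks. The genes were chosen by the authors, so the share says nothing about transcripts outside the table. The median log2 fold change was -1.47, with quartiles at -1.75 and -1.26, which is 2.78-fold lower at the median. In 26 of the 31 peaks the value lay at or below -1. The remaining 5 peaks, with milder changes, were in Atg5, Ppp2cb, Atg101, Atg4a and Ppp2ca.

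Rb1cc1, which encodes the FIP200 scaffold of the ULK1 kinase complex, had the lowest peak, at -3.60 on the log2 scale or 12.1-fold lower. That peak covers bases 6274960 to 6275122 of chromosome 1 (mm10) in the 3' UTR. The Rb1cc1 peaks in exon 7 and exon 15 changed less, with log2 fold changes of -1.34 and -1.74. Of the other members of the initiation kinase group, the 3' UTR peak of Ulk3 (chromosome 9, 57595013 to 57595454) was at -2.12, that of Ulk1 (chromosome 5, 110785578 to 110786182) at -1.75 and that of Atg13 at -1.31. Atg101 had a 5' UTR peak at -0.78 and a last-exon peak at -1.27. The 8 peaks of these 5 genes had a median of -1.54.

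The 3 genes of the class III phosphatidylinositol 3-kinase complex had a median of -1.64 over 5 peaks. Pik3r4, the regulatory subunit, fell in exon 4 (-2.03) and in exon 2 (-1.31), the catalytic subunit Pik3c3 fell in its 3' UTR (-1.95), and Uvrag fell in its 3' UTR (-1.64) and last exon (-1.20). In the lipid transfer and scrambling group, Atg9a had a 3' UTR peak at -2.12, while Atg2b and Atg2a were at -1.28 and -1.24. In the ATG12 conjugation group, both Atg12 peaks (-1.67 in the 3' UTR and -1.51 in exon 1) and the Atg16l2 3' UTR peak (-1.23) fell further than the Atg5 3' UTR peak, which had the smallest change of the table (-0.55, or 1.46-fold lower).

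The LC3 family and its proteases had a median of -1.48 over 7 peaks in 5 genes. Atg4c had the second lowest peak of the table, in exon 5 (-2.17), and another in the last exon (-1.47), whereas the last-exon peak of Atg4a was at -0.90. Map1lc3b had last-exon peaks at -1.75 and -1.48, Map1lc3a a 5' UTR peak at -1.56 and Gabarapl1 a last-exon peak at -1.29. The remaining genes were the catalytic subunits of protein phosphatase 2A, Ppp2ca (-1.85 in the last exon, -0.95 in the 5' UTR) and Ppp2cb (-0.66 in the 5' UTR), and the lysosomal membrane protein gene Dram2 (-1.44). The assignment of the 22 genes to these steps was made after the table was seen.

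**Figure D1:**
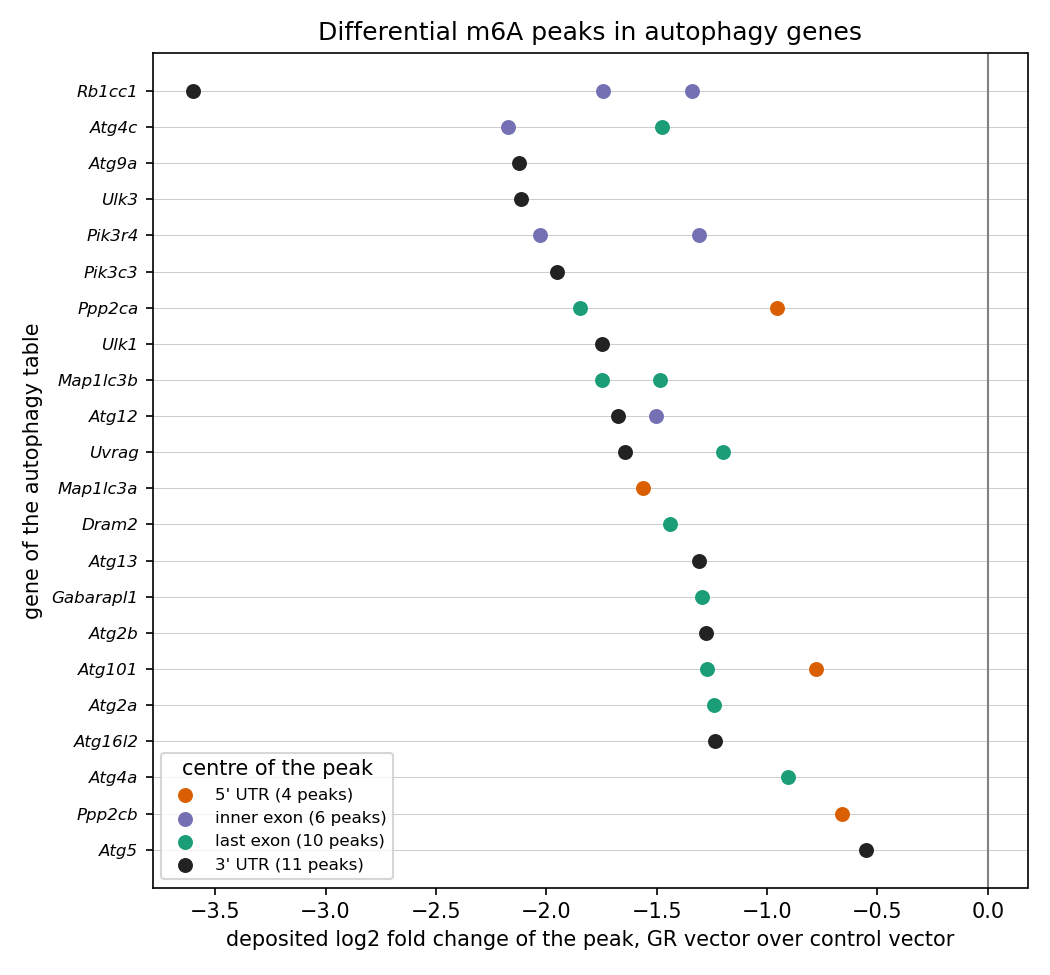
Deposited log2 fold change of each of the 31 peaks (horizontal axis, GR vector over control vector) by gene (vertical axis), with the gene part at the centre of the peak in colour. Every point lies below 0, from -0.55 in Atg5 to -3.60 in Rb1cc1, and the 5' UTR peaks of Ppp2ca, Atg101 and Ppp2cb lie near the right edge.

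By the gene part at the centre of the peak, 11 of the 31 peaks were in a 3' UTR, 10 in a last exon, 6 in another exon and 4 in a 5' UTR. At 35.5%, the 3' UTR share rose to 58.1% when the end of the peak was taken in place of its centre. The 4 peaks centred in a 5' UTR (Atg101, Map1lc3a, Ppp2ca and Ppp2cb) had the mildest median, -0.86, against -1.67 for the 3' UTR, -1.37 for the last exon and -1.62 for other exons. The Map1lc3a peak of this group, at -1.56, lay below the median of all peaks, and the grouping was singled out after the values were seen. In 8 genes with several peaks, 7 had peaks in gene parts that could be ordered, and in 6 of these (Atg101, Atg12, Pik3r4, Ppp2ca, Rb1cc1 and Uvrag) the peak nearest the 3' end was the lower one. Atg4c went the other way, with its exon 5 peak 0.70 below its last-exon peak on the log2 scale.

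A second table lists genes related to differential peaks, without direction, size or position. Its 17052 lines held 9225 distinct Ensembl gene IDs, of which 5127 occurred on 1 line. What a line stands for is not stated. By reference names, 3278 IDs carried an unnamed gene model (Gm-number, Rik and the like) and 5939 another symbol, microRNA genes such as Mir3061 included. The reference gave a gene class for 7282 IDs. Besides protein-coding genes, these were mainly long non-coding RNAs (628), pseudogenes (618), microRNAs (249), small nucleolar RNAs (98) and small nuclear RNAs (96). Of the 21900 protein-coding genes in the reference, 5526 (25.2%) were listed, against 4 of 1110 olfactory receptor genes. The clustered protocadherins led the number of lines among named genes, with 39 for Pcdha11 and 34 for Pcdhac2. Zbed6 had 16 lines, Map1lc3b 14 and Taf7 12.

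The gene table and the autophagy table overlapped in part. Only Atg101, Atg12, Atg16l2, Atg4c, Map1lc3a, Map1lc3b, Pik3c3, Pik3r4 and Ulk3, 9 of the 22 autophagy genes, were in the gene table. The other 13, Rb1cc1, Ulk1, Atg13, Atg2a, Atg2b, Atg4a, Atg5, Atg9a, Dram2, Gabarapl1, Ppp2ca, Ppp2cb and Uvrag, were not, although they account for 17 of the 31 peaks. Absence of a gene from the gene table therefore did not mean that it lacked a differential peak. Of the 9 genes in both, only 2 had as many lines as peaks. Map1lc3b had 2 peaks and 14 lines, and Atg12 had 2 peaks and 1 line. The number of lines given for a gene is therefore not a measure of its peaks or of its m6A change. In the other direction, 12 genes of a core autophagy list of 44 were in the gene table and not in the autophagy table, among them Becn1, Ambra1, Atg3, Atg4d, Gabarap and Wdr45b. No peak position, fold or direction is given for these genes. Of the 44, 18 were in the autophagy table and 14 in neither, such as Atg7, Atg14, Atg16l1, Ulk2 and Wipi2.

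Fixed gene lists were described by the share of their genes in the gene table, with the exact 95% interval of each share covering counting error only. Being listed is a weak sign of a differential peak. Of the 22 genes with deposited peaks in the autophagy table, 40.9% were listed, above the 25.2% of all protein-coding genes. That was no more than the 45.5% of the core autophagy list, which also holds genes outside the autophagy table. The shares below thus count listed genes, not genes shown to change in m6A. Percentiles among 10000 random lists matched on gene length describe these libraries. The random lists come from all protein-coding genes, since the genes with enough RNA for a peak are not given, and whether expression sets the rank of a list was not tested. The share was 62.5% (43.7% to 78.9%) for beta-cell identity and insulin synthesis, where 20 of 32 genes were listed, more than in nearly all random lists. Slc30a8 had 6 lines, Mafa and Nkx2-2 had 4 each, Nkx6-1, Pax6, Pcsk2 and Slc2a2 had 3, Pdx1 had 2 and Ins1 had 1, whereas Ins2, Neurod1, Iapp and Glp1r were absent. Among insulin granule and ion channel genes, 16 of 28 (57.1%) were listed, with Chga, Chgb, Kcnj11 and Syt7 on 3 lines each and Abcc8, Cacna1c and Cacna1d absent. Wnt and TGF-beta signalling had 19 of 31 (61.3%), led by Bcl9 with 4 lines.

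The machinery that writes, removes and reads m6A was itself listed for 13 of 23 genes (56.5%, 34.5% to 76.8%, 99.8th percentile). Ythdc1 had 6 lines, Mettl3, Rbm15b and Zc3h13 had 3 each, and Wtap, Alkbh5, Ythdf1, Ythdf2, Ythdf3 and Ythdc2 were also present, while Mettl14, Fto, Virma, Cbll1 and the Igf2bp genes were absent. Nr3c1, the glucocorticoid receptor gene, was not in the gene table. Its list holds known target genes together with chaperone and cofactor genes, and 14 of 32 (43.8%, 99.1st percentile) were listed. The share is thus not one of target genes alone. Listed were, among others, Tsc22d3, Dusp1, Per1, Klf9, Txnip, Errfi1, Cebpd, Cebpb, Nfkbia and the chaperone genes Hsp90aa1 and Hsp90ab1. Fkbp5, Sgk1, Zbtb16, Pdk4, Pck1 and the cofactor genes Ncoa2, Ncor1, Crebbp and Ep300 were not.

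Core autophagy machinery had 20 of 44 genes listed (45.5%, 30.4% to 61.2%, 99.7th percentile) and selective autophagy receptors 8 of 22 (36.4%, 83.5th percentile), with Sqstm1 and Bnip3l on 2 lines each and Nbr1, Optn and Tax1bp1 absent. The lysosome and TFEB programme had 13 of 29 (44.8%), with Tfe3, Ctsb and Ctsl listed and Tfeb, Lamp1 and Lamp2 absent. Of the mTOR, AMPK and insulin signalling genes, 14 of 36 (38.9%) were listed, led by Prkag1 with 7 lines and Irs2 with 6, and Mtor, Rptor, Insr and Foxo1 were absent. Other shares were 53.3% for the cell cycle (Ccne2 6 lines, E2f1 4), 52.0% for apoptosis and p53 (Bax 4 lines), 50.0% for the unfolded protein response (Wfs1 5 lines, Ddit3 3) and 50.0% for chromatin modifiers (Setd1b 10 lines). The circadian clock had 8 of 20 genes (40%, 90.3rd percentile), among them Nr1d1 with 4 lines.

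Lists at or below the share of random lists were ribosomal proteins with 9 of 33 genes (27.3%, 45.1st percentile), the respiratory chain with 7 of 29 (24.1%, 24.2nd percentile, Ndufs3 on 8 lines) and markers of other islet endocrine cells with 3 of 12 (25.0%, 45.7th percentile), namely Gcg, Ttr and Pou3f4. Markers of exocrine, ductal, mesenchymal and blood cells had the lowest share, 3 of 24 genes (12.5%, 3.01st percentile). In all, 12 of the 18 lists lay above the 95th percentile.

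**Figure D2:**
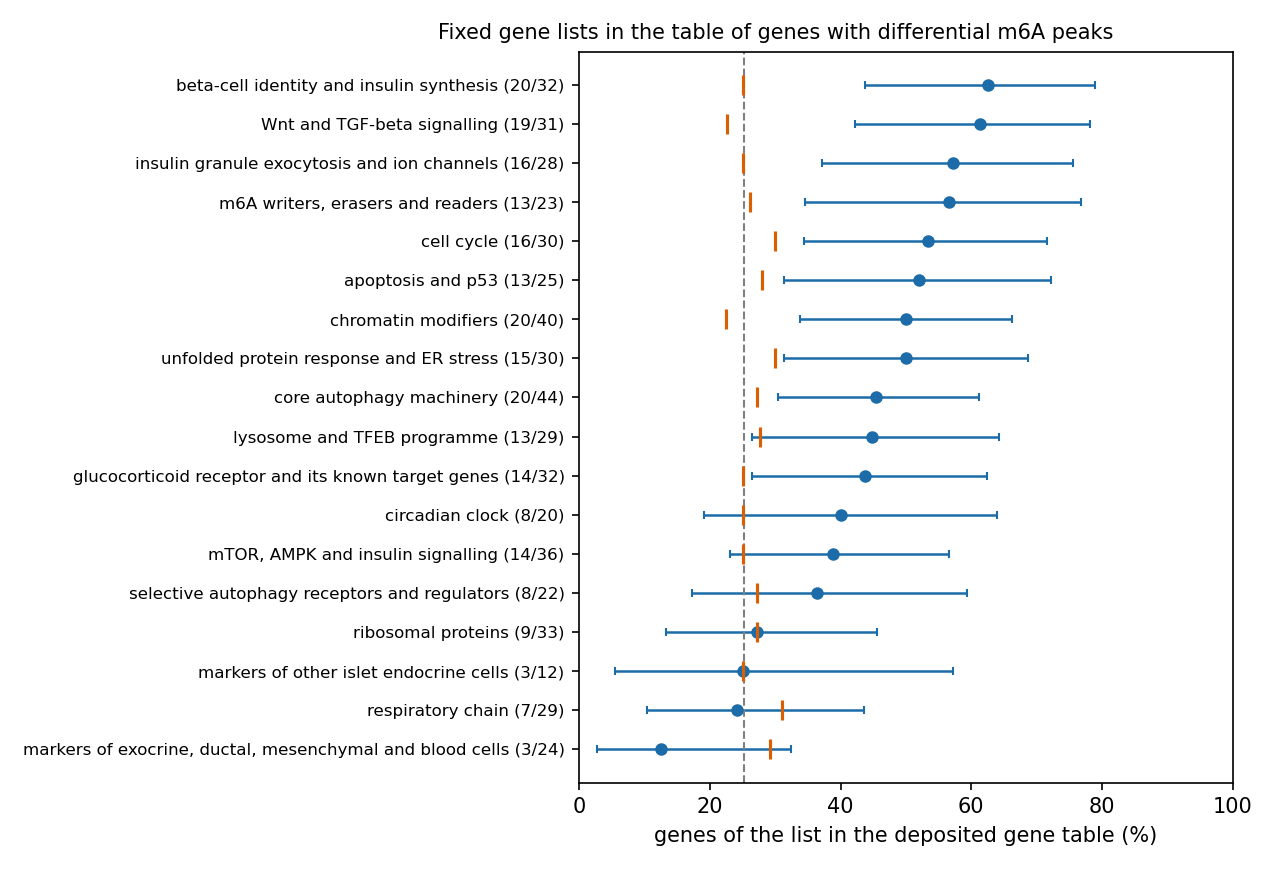
Share of each fixed list that was in the deposited gene table (points, percent) with exact 95% Clopper-Pearson intervals (bars), the median share of 10000 length-matched random lists (orange ticks) and the share of all protein-coding genes (dashed line, 25.2%). Labels give genes listed and genes in the list. Beta-cell identity genes had the highest share, 62.5%, and markers of exocrine, ductal, mesenchymal and blood cells the lowest, 12.5%.

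The deposited KEGG pathway table held 290 pathways, 194 of them with an adjusted p below 0.05 in the authors' deposited table. The smallest p in the authors' deposited table, 1.53e-41, belonged to metabolic pathways, with 503 input IDs (428 distinct Entrez genes) against 1298 genes in the background. HIF-1 signaling followed with 102 input genes against 110 in the background and p = 1.61e-28 in the authors' deposited table. The input is counted by Ensembl gene ID, and these 102 IDs mapped to 53 distinct Entrez genes, with 30 IDs mapped to Gapdh and 13 to Rps6. Of the 30, 1 was Gapdh itself and 29 were unnamed gene models, 20 of which the reference classes as pseudogenes. Gapdh with its 29 models was also counted in metabolic pathways, Alzheimer's disease (123 IDs, 72 genes), carbon metabolism (81 IDs, 45 genes) and biosynthesis of amino acids (63 IDs, 27 genes), the latter 3 at ranks 3 to 5. Ranks 6 to 10 were pathways in cancer (161 IDs, 141 genes), spliceosome (80 IDs, 67 genes), Huntington's disease (100 IDs, 79 genes), PI3K-Akt signaling (144 IDs, 120 genes) and RNA transport (89 IDs, 79 genes).

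**Figure D3:**
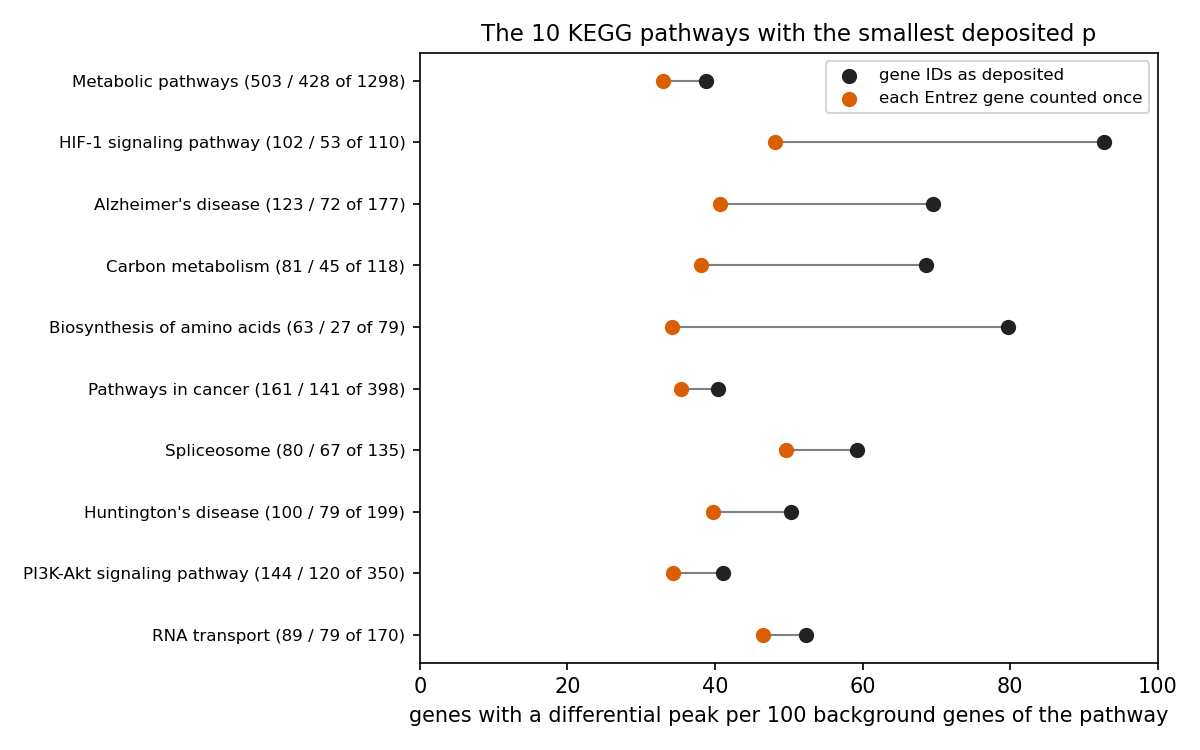
Input genes, listed by the authors as related to differential peaks, per 100 background genes (horizontal axis) for the 10 KEGG pathways with the smallest deposited p. They are counted as gene IDs (black) and with each Entrez gene once (orange). Labels give both counts and the background. HIF-1 signaling went from 102 to 53 genes against a background of 110, while RNA transport went from 89 to 79 against 170.

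Among pathways close to the study's subject, chosen after their values were seen, mTOR signaling had 84 input IDs (69 genes) against 156 and insulin signaling 78 (62 genes) against 142, with p = 1.51e-13 and p = 5.09e-13 in the authors' deposited table. Insulin secretion had 36 against 86 (p = 8.55e-05), type II diabetes 23 against 50 and lysosome 47 against 124 in the authors' deposited table. Regulation of autophagy had 11 input genes against 40, with p = 0.166 and an adjusted p of 0.213 in the authors' deposited table. Those 11 were Becn1, Atg16l2, Ins1, Atg12, Pik3r4, Pik3c3, Atg4d, Ulk3, Atg3, Atg4c and Gabarap, so the pathway was counted without Ulk1, Atg13, Atg5 and Gabarapl1, which have lower peaks in the autophagy table. Olfactory transduction, with 24 input genes against 1102, was at the bottom.

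In the Gene Ontology (GO) table, all 16568 terms had a p of 1 in the authors' deposited table, before and after adjustment, so no term could be ranked by p. One-sided hypergeometric p-values recomputed from the 4 counts of each term had a median of 0.925, with 17 terms below 0.05 before and 0 after Benjamini-Hochberg adjustment. The table gives 10022 genes with a peak among 20770 in the background, 48.3%, but the gene lists of its terms held 5409 distinct IDs, 26.0% of the background. With the distinct IDs as total, a setting added after seeing the data, 1111 terms were below 0.05 after adjustment. The calls thus depend on which total is used. All 5409 IDs were in the gene table, whereas the deposited 10022 exceeds even the 9225 distinct IDs of that table. It therefore cannot be a count of those IDs, and what it counts is not stated. The large p-values under that total do not show a lack of enrichment. Terms named here were chosen after their counts were seen. All 7 genes of N6-methyladenosine-containing RNA binding were listed (Hnrnpa2b1, Hnrnpc, Ythdc1, Ythdc2, Ythdf1, Ythdf2 and Ythdf3). Macroautophagy had 76 of 187 genes (40.6%), autophagosome assembly 38 of 92 (41.3%) and autophagy 132 of 367 (36.0%). These shares lay above 26.0% but below the 48.3% of the deposited totals, which rests on the unexplained 10022. Terms further from the study's subject had like shares, such as mRNA processing with 186 of 450 (41.3%) and DNA repair with 177 of 435 (40.7%). Mitophagy had 9 of 20 (45.0%), with an exact 95% interval of 23.1% to 68.5% that includes the 26.0% share. Glucose homeostasis had 105 of 273 genes (38.5%), insulin secretion 79 of 211 (37.4%) and lysosome 136 of 417 (32.6%). Response to glucocorticoid, with 51 of 181 genes (28.2%), was closer to the 26.0% share, and sensory perception of smell had 12 of 1195 (1.00%).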

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

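The number of lower autophagy peaks (31) stayed within 1.5 times under each of these settings: a limit of 1 on the absolute log2 fold change, genes in place of peaks, no unnamed models, no peaks of the widest 10% and merged peaks, with counts from 22 to 31. Each setting only keeps, drops or groups rows of the same table, so these counts do not show stability. The median log2 fold change of -1.47 was -1.60 with the largest fold of each gene and -1.43 with the mean of each gene. The share of lower peaks among core autophagy genes was 100%, which no subset of a table with 0 higher peaks can change, so those settings say nothing about its stability. Of the 18 gene lists, 12 lay above the 95th percentile with and without matching on length, and matching by deposited symbol, added later, moved none of the 18 shares beyond its interval. The share of the autophagy table in the gene table (40.9%) was within its interval for the fixed core list (45.5%) and the KEGG autophagy pathway (27.5%). These are unlike measures, so their overlap does not show stability. Every gene of the autophagy table has a deposited peak, whereas the core list and the pathway also hold genes outside that table.

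The 3' UTR share of peaks, 35.5%, was 50% with 1 peak per gene, within its interval. The peak kept was the one with the largest absolute fold. That rule can favour 3' UTR peaks, which had the lowest median (-1.67), so it is not a neutral check of position. The share moved to 58.1% with the end of the peak in place of its centre, an alternative chosen after seeing the data. Peaks such as those of Atg2a and Atg4a were centred in the last exon and ended in the 3' UTR. The 9225 gene IDs became 17052 when lines were counted and 5939 without unnamed gene models, by construction. The 194 KEGG pathways were 194 with recomputed p-values, 193 with 10 to 500 background genes and, added later, 172 with each Entrez gene counted once. The 0 GO terms stayed 0 with p-values from the 4 deposited counts, and became 1111 with the number of distinct IDs as total, or 735 among terms with 10 to 500 background genes, 2 settings added after seeing the data. The counts rise by construction, since the 5409 distinct IDs make a smaller total than the deposited 10022.

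A stricter p or q for peaks was not run, since the table gives none. No paired analysis was possible because each arm has 1 library of each kind, which also rules out leaving a library out. Depth is unknown, and its limits were not judged.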

Other observations

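The tests of explanations in this part were chosen after the results were seen.

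All 31 peaks of the autophagy table were lower with GR. A loss of m6A caused by GR is the biological explanation that the design names, and it was not tested, because each arm has 1 IP library. A factor common to all peaks, such as a lower IP yield in the GR arm, could also give 31 negative values. The folds had an SD of 0.57 between peaks, and the Rb1cc1 peaks alone differed by up to 2.26 on the log2 scale. The error of a single fold is not given, so a common factor plus noise cannot be told apart from changes particular to each peak. A fall in RNA level and the choice of genes for the table stay open too, since no input value and no fold of any other gene was used here.

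The absence of Rb1cc1, Ulk1, Atg5 and 10 other autophagy-table genes from the gene table was weighed next. A search by Ensembl ID, symbol and synonym found 0 of the 13, which argues against another name for the same gene. A candidate explanation is that lines were given to a neighbouring gene. The nearest other gene was in the gene table for 7 of the 13 absent genes and for 2 of the 9 present genes. Its lines equalled the peaks in number for Rb1cc1, Ppp2ca, Atg13, Atg2a and Atg2b, but not for Ulk1 (1 peak, 5 lines of Gm26515) or Atg9a (1 peak, 2 lines of Abcb6). Among the 9 present genes, a gene's own lines equalled its peaks in only 2, so equal numbers say little about a shift. These neighbours lay from 1282 bases (Abcb6) to 23592 bases (4732440D04Rik, near Rb1cc1) from the nearest peak. Random unlisted genes of like length gave a median of 3, which put 7 at the 99.4th percentile. Against 249 unlisted members of the fixed lists, which are closer in kind, the median was 4 and 7 lay at the 95.2nd percentile, short of the limit set for the test. A shift of lines to neighbours cannot be told apart from chance in these 13 genes, and the strand of genes, which decides the nearest start, was not used here. No biological explanation was tested.

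The top KEGG pathways were weighed against 2 properties of the counting. With several gene IDs counted per gene as the cause, pathways should leave the top once each Entrez gene is counted once. Of the 10 pathways with the smallest deposited p, 4 stayed among the 10 smallest (metabolic pathways, pathways in cancer, spliceosome and RNA transport). HIF-1 signaling went from rank 2 to 15, carbon metabolism from 4 to 70 and biosynthesis of amino acids from 5 to 140. Their recomputed adjusted p-values stayed below 0.05 (1.39e-06, 3.04e-04 and 0.0129, one-sided Fisher), so the repeated IDs may explain their rank and not their call. The input total of 7193 was kept, and repeats in it could not be removed. Reads shared between Gapdh and its pseudogenes are a candidate source of the repeats, which no value per library could test.

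A background of all annotated genes may raise most pathways at once. With each Entrez gene counted once, 257 of the 290 pathways still lay above the background share, with a median ratio of 1.89. Before repeats were removed, 261 did. A wide reach of m6A change, the biological explanation, would give the same, and no file gives the genes that the cells expressed, so a wide background cannot be told apart from it.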
